A study of Mus musculus with 24 samples.

How the data were processed

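Chromatin accessibility had been profiled by ATAC-seq (sequencing of DNA that the Tn5 transposase cuts in open chromatin) in 24 libraries of CD90.2+ T cells from the blood of mice. Per the labels, the cells came from the flow-through left after CD19+ B cells were bound to magnetic columns, were then bound with CD90.2 microbeads, and were tagmented with digitonin in parallel with the B cells. The deposited table holds raw counts per peak for each library, with no normalisation, on mm10 coordinates. Picard, SAMtools, MACS2 and featureCounts are named in the authors' processing notes, without a version, a setting or the step each one served. Whether reads or fragments were counted, how peaks were merged, and whether peak starts count from 0 or from 1 are not given in the sources used here. Every column was matched to 1 library by its name, and 0 columns were left over.

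Groups were taken from the sample titles and genotype labels. They gave 11 wild-type libraries, 6 libraries of Kmt2d+/βGeo mice (the model of Kabuki syndrome type 1) and 5 libraries of Kdm6a+/- mice (the model of Kabuki syndrome type 2). For 2 further libraries the title and the genotype label contradict each other, with column names in the deposited table that side with the titles, so they entered no comparison, and their values are given only among the closing observations. Sample names came in 2 formats, 1 with T and 1 with CD90-2, whose meaning the labels do not state. The T format covered 5 wild-type, 4 Kmt2d+/βGeo and 5 Kdm6a+/- libraries, and the CD90-2 format covered 6 wild-type and 2 Kmt2d+/βGeo libraries, so no Kdm6a+/- library had the CD90-2 format. The labels do not state whether each library came from a separate animal, so p-values measure the spread between these libraries.

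Library totals in peaks ran from 6.9 to 27.8 M counts, and no pair of libraries was a copy of another. The median biological coefficient of variation per peak was 23.7%. A count filter (filterByExpr of edgeR) kept 93053 of the 93446 peaks. Counts were scaled by TMM factors and tested with the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, with terms for name format and group, all 22 libraries in 1 fit and 18 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested peaks of a comparison, with a threshold of 0.05. Standard errors of log2 fold changes (SE) were derived from the test statistic, and levels are TMM-scaled counts per library size (CPM) as mean ± SD over libraries. Simulated data held 200 changed peaks, drawn from those above the median mean count and divided equally between 1.5-fold and 2-fold changes. For Kmt2d+/βGeo against wild type, 47% of 1.5-fold and 85% of 2-fold changes were recovered, with 10 false calls. For Kdm6a+/- against wild type 27% and 85% were recovered with 6 false calls, and between the models 25% and 77% with 4.

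Peaks were placed on 21905 RefSeq genes of GRCm38.p6, which shares its coordinates with mm10. The gene table gave no strand, so a peak within 1 kb of either end of a gene was called a gene-end peak, in place of a promoter peak. Of the peaks, 15789 were at gene ends, 43303 in gene bodies and 34354 intergenic. Peaks were named by the gene at whose end they lay, else by the gene that held them, else by the nearest gene, which need not be the gene they act on. Before the data were examined, 19 gene lists with 382 genes were fixed, and 346 of these genes had a gene-end peak. They covered T cell receptor and lineage genes, naive and central memory, effector and memory, exhaustion and aging, regulatory T cell, trafficking, interferon, immediate early, cell cycle, ribosomal protein and X-escape genes. They also covered H3K4 methyltransferase complexes with H3K27 demethylases, Polycomb complexes, Polycomb-target developmental transcription factors, acetylation and DNA methylation enzymes, and markers of B, myeloid, NK and erythroid cells. Lists and region classes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over 19 lists or 5 classes.

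The rule for named genes was set at the same time. It took the gene-end peaks of Kmt2d and Kdm6a, the 10 largest changes in each direction among called peaks above the median abundance, the 5 smallest p-values, and up to 4 genes of each list. Where no peak passed, the 5 smallest p-values in each direction were named as not passing. Enrichment of called peaks in a region class was tested with Fisher's exact test against all tested peaks, and measures per library with exact permutation tests. Agreement of the models was compared with 20 simulations of unchanged groups that shared the wild-type libraries, and with wild-type libraries divided between the models in 20 draws.

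Alternatives were RLE factors, total counts, loess normalisation, DESeq2 1.42.0, limma voom with quality weights, no count filter, a mean of at least 20 counts, no name-format term, each name format alone, 2 surrogate variables (sva 3.50.0), a replicate-number block, a threshold of 0.1, autosomes alone, only the groups compared, a gene-end distance of 2 kb, and each library left out in turn. After the data were seen, a term for libraries over 20 M counts, a fit without them, a fit without them and without Kmt2d+/βGeo replicate 7, and a fit without peaks within 10 Mb of Kmt2d were added. Group labels were also redrawn within name format, for 64 splits of each comparison with the real one included. Tables used the R package data.table (version 1.17.8), and annotation and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No genome sequence was used here, so CpG-island classes and a correction for GC content were left out.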

Results

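Accessible chromatin was measured in CD90.2+ T cells from the blood of wild-type mice, of Kmt2d+/βGeo mice and of Kdm6a+/- mice. Kmt2d encodes a histone H3K4 methyltransferase and Kdm6a a histone H3K27 demethylase, and loss of a copy of either gene causes Kabuki syndrome. There were 11 wild-type, 6 Kmt2d+/βGeo and 5 Kdm6a+/- libraries. Totals in peaks were 6.9 to 27 M counts in wild type (median 12.1), 7.1 to 27.2 M in Kmt2d+/βGeo (median 14.15) and 15.4 to 18.7 M in Kdm6a+/- (median 16.1). Wild-type replicates 3 and 6 and Kmt2d+/βGeo replicate 2 each had over 20 M counts and stood apart on the first principal component, at 95.5 to 124.4. Kmt2d+/βGeo replicate 7 (7.1 M counts) lay furthest out, at 172 on the first and -205.8 on the second component, and had 5042 peaks at a count of 0, where the next highest library had 618. Among 93446 peaks with a median width of 676 bp, 93053 were tested.

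The targeted genes were measured first, at their gene ends. The peak 970 bp from an end of Kmt2d (15:98832639-98832995) had 9.19 ± 2.04 CPM in wild type (SD, n = 11), 7.85 ± 1.16 in Kmt2d+/βGeo (n = 6) and 7.34 ± 0.821 in Kdm6a+/- (n = 5). Its log2 fold change was -0.18 ± 0.14 (SE) in Kmt2d+/βGeo and -0.24 ± 0.16 in Kdm6a+/- against wild type. The peak shared with the end of Prkag1 (15:98830682-98832034), a gene for a subunit of AMP-activated kinase, had 69.4, 71.6 and 69.6 CPM in the same order. At Kdm6a (X:18161628-18164443) the levels were 187 ± 13.4, 192 ± 25.5 and 188 ± 13.7 CPM. None of these 3 peaks was called by edgeR in any comparison. Both peaks at Kmt2d lay at the same end of the gene (98831669). No tested peak lay within 1 kb of its other end (98874077), so that end was not measured. Accessibility at a gene end is not a measure of the copies of a gene.

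Kmt2d+/βGeo was compared with wild type to ask which regulatory regions of T cells differ when a copy of Kmt2d is disrupted. The gene end of Map2, which encodes a microtubule-associated protein of neurons, was 2.79-fold higher, at 20.5 ± 4.42 CPM (SD, n = 6) against 7.3 ± 1.53 (n = 11). A peak 1357 bp from Mfng, whose product adds sugars to Notch receptors, was 2.61-fold higher, at 13.3 against 5.16 CPM. The gene end of Kitl, the ligand of the receptor Kit, was 2.21-fold higher, at 5.48 against 2.51 CPM. A peak inside Ntrk2, the gene of a receptor for brain-derived neurotrophic factor, was 4.93-fold lower, at 1.24 ± 0.384 against 5.9 ± 1.34 CPM. Across the genome edgeR called 302 peaks, of which 211 were higher and 91 lower in Kmt2d+/βGeo.

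Among the 10 largest gains at peaks of above-median abundance, Map2 (1:66174748-66175934) had a log2 fold change of 1.48 ± 0.13 (adjusted p = 1.76e-08) and Mfng (15:78752441-78754525) one of 1.39 ± 0.14 (adjusted p = 1.6e-07). A peak 159616 bp from Prickle1, a planar cell polarity gene (15:93755882-93756597), followed with 1.34 ± 0.16 (adjusted p = 4.52e-06), and a peak in Adgrl2, an adhesion G protein-coupled receptor gene (3:148913331-148914186), with 1.29 ± 0.15 (adjusted p = 5.9e-06). Kitl (10:100015512-100016701) had 1.15 ± 0.2 (adjusted p = 0.00247), and the gene end of Gm21814 (6:149565553-149567013) had 1.1 ± 0.12 (adjusted p = 9.11e-07). The gene end of Susd4, a regulator of complement (1:182763565-182764864), and a peak in Gxylt1, whose enzyme adds xylose to Notch (15:93251248-93252716), both had 1.09. The others were a peak in Fhit, a gene at a fragile site (14:10911323-10912073), at 1.19 ± 0.23 (adjusted p = 0.00792), and a peak near the kinase gene Plk2 (13:110683190-110684326), at 1.12 ± 0.2 (adjusted p = 0.00324). Every one of these 10 peaks lay above the wild-type median in 6 of 6 Kmt2d+/βGeo libraries. The Fhit and Plk2 calls ended when Kmt2d+/βGeo replicate 7 was left out (adjusted p = 0.0599 and 0.0534), and with the T format alone or a replicate-number block. Kitl ended with the T format alone and without the deep libraries and replicate 7, as did Plk2. Over their alternatives the adjusted p of Fhit, Kitl and Plk2 went up to 0.302, 0.317 and 0.337. With the CD90-2 format alone, the calls of Map2 and Mfng held and the other 8 ended.

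Among peaks of above-median abundance, losses were led by Ntrk2, where peaks at 13:59025355-59026251 and 13:59011231-59011968 had log2 fold changes of -2.3 ± 0.21 (adjusted p = 1.76e-08) and -2.12 ± 0.23 (adjusted p = 1.32e-06). A peak in Dysf, the gene of a membrane-repair protein (6:84178713-84179390), had -1.36 ± 0.23 (adjusted p = 0.00225). A peak in Sufu, an inhibitor of Hedgehog signalling (19:46454247-46455498), had -1.22 ± 0.19 (adjusted p = 0.000648). A region 321667 bp from Tbx3, a developmental transcription factor gene (5:119348019-119348867), fell from 12.2 to 5.62 CPM (log2 fold change -1.12 ± 0.13, adjusted p = 8.21e-06). The cadherin gene Cdh22 (2:165166811-165167949), the gene end of Prkrip1 (5:136179393-136180125), the nuclear export gene Xpo4 (14:57611006-57611688) and a region near the olfactory receptor gene Olfr1509 (14:52436538-52437471) had -1.12, -1.11, -1.1 and -1.07. Another region, 94243 bp from Ntrk2 (13:59228213-59229457), had -1.1 ± 0.24 (adjusted p = 0.0284). Its call ended without Kmt2d+/βGeo replicate 4 (adjusted p = 0.0695), 5 (0.0836), 6 (0.077) or 7 (0.114). With the T format alone its call and those of Dysf, Sufu, Cdh22, Prkrip1, Xpo4 and Olfr1509 ended, and those of this region, Cdh22 and Olfr1509 also ended without the deep libraries and replicate 7. This region also ended with limma voom and Cdh22 with a replicate-number block, and the CD90-2 format alone ended 9 of the 10 calls, all but 13:59011231-59011968. The highest adjusted p over the alternatives of each of these 9 ran from 0.103 for 13:59025355-59026251 to 0.523 for Olfr1509. All 10 lay below the wild-type median in 6 of 6 Kmt2d+/βGeo libraries.

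**Figure D1:**
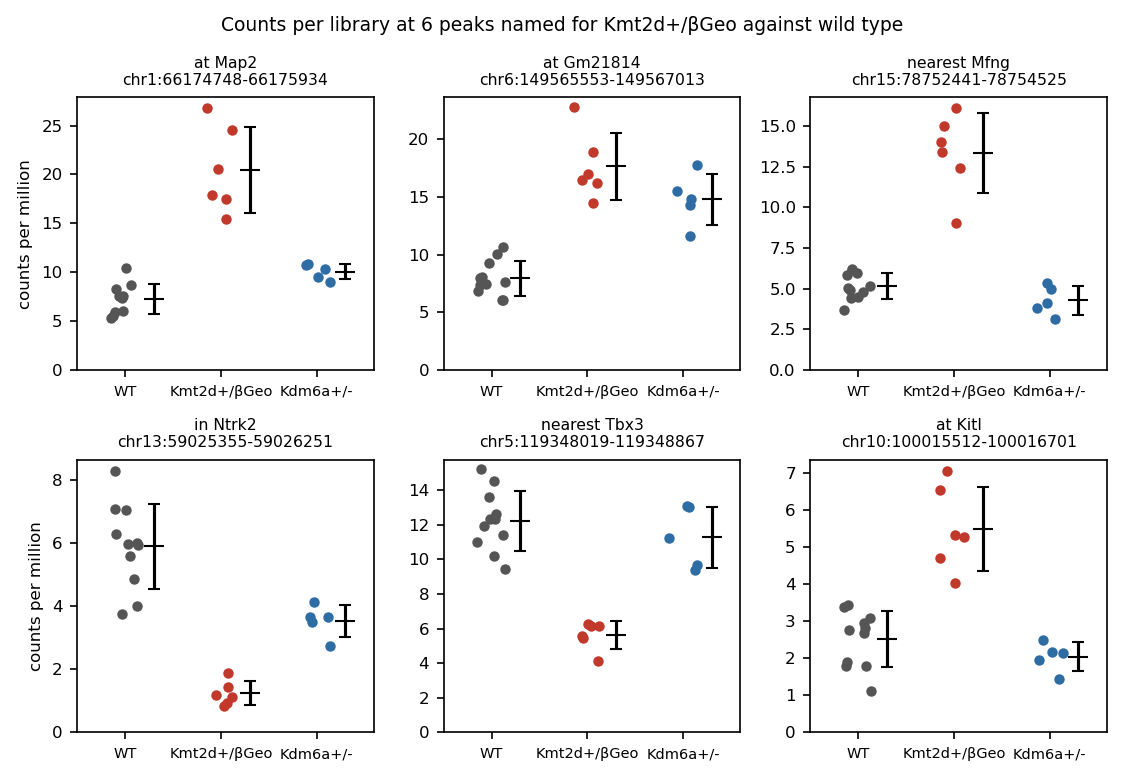
TMM-scaled CPM of each library (points) at 6 named peaks in wild type (n = 11), Kmt2d+/βGeo (n = 6) and Kdm6a+/- (n = 5), with the mean (line) and SD (bars). At Map2 the Kmt2d+/βGeo libraries lie between 15.4 and 26.8, above all wild-type libraries (5.32 to 10.4), and at the peak in Ntrk2 they lie between 0.852 and 1.9.

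Gains were concentrated at gene ends and losses were not. Of the 211 higher peaks, 72 (34.1%) lay at gene ends, against 16.9% of all tested peaks (Fisher's exact test, odds ratio 2.55, 95% interval 1.89 to 3.41, adjusted p = 8.3e-09). Of the 91 lower peaks 6 (6.6%) lay at gene ends (odds ratio 0.35, adjusted p = 0.018) and 56 (61.5%) in gene bodies (odds ratio 1.85, adjusted p = 0.018). The rest of the 211 gains were 77 in gene bodies (odds ratio 0.66, adjusted p = 0.0112) and 62 intergenic (odds ratio 0.72, adjusted p = 0.0445). Gene ends, gene bodies and intergenic regions together hold every peak, so an excess at gene ends lowers the other shares. These lower shares are therefore not separate results. Over all gene-end peaks the median log2 fold change was 0.05 and camera gave an adjusted p of 0.000121, which became 0.25 with an estimated correlation. The share of counts at gene ends was 53.12 ± 1.357% in Kmt2d+/βGeo (n = 6) and 52.61 ± 0.6607% in wild type (n = 11; two-sided exact permutation p = 0.3, adjusted p = 0.942 over 18 tests). Within the T format it was 53.98 ± 0.3211% (n = 4) against 52.82 ± 0.639% (n = 5; exact permutation p = 0.0159, adjusted p = 0.285). With loess normalisation the camera adjusted p was 0.933 and the odds ratio of gene ends among gains was 1.41 (95% interval 1.01 to 1.93). That odds ratio was 1.6 without wild-type replicate 3 (1.23 to 2.06, 24.6% of 334 gains) and 1.64 without the deep libraries (1.29 to 2.07, 25.1% of 390 gains). With a mean of at least 20 counts it was 1.91 (1.38 to 2.61), and over 34 alternatives it ran from 1.41 to 3.47. Fisher's exact test did not match peaks for abundance, and gene-end peaks hold more counts per peak than others. How far easier detection raised their share of gains was not tested. Of the X-linked peaks, 9 were higher and 0 were lower by edgeR (odds ratio of gains 1.66, adjusted p = 0.162).

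Peaks within 10 Mb of Kmt2d were called more often than others, though not at the gene itself. Within 10 Mb of Kmt2d on chromosome 15, 18 of 907 tested peaks were called (1.98%), against 0.31% elsewhere (Fisher's exact test, odds ratio 6.55, 95% interval 3.81 to 10.6, p = 1.65e-09). Of the 18, 17 were higher in Kmt2d+/βGeo, and the exception was a region 38409 bp from Pced1b, at a log2 fold change of -0.62 ± 0.11. This exception was the called peak nearest to Kmt2d, at 1.41 Mb. Called peaks in or near Gxylt1, Yaf2, Prickle1 and Adamts20 lay together, 4.63 to 5.58 Mb from Kmt2d. Fisher's exact test takes such neighbours as independent, so its p-value is too small if they change together. The following peaks there were chosen after their values were seen. Regions 164169 and 176977 bp from Prickle1 had 2.64 ± 0.28 and 2.76 ± 0.34, and regions near the amino acid transporter genes Slc38a1 and Slc38a2 had 2.33 ± 0.48 and 2.31 ± 0.29. Of the 19 peaks that differed between Kmt2d+/βGeo and Kdm6a+/-, 5 lay within these 10 Mb.

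**Figure D2:**
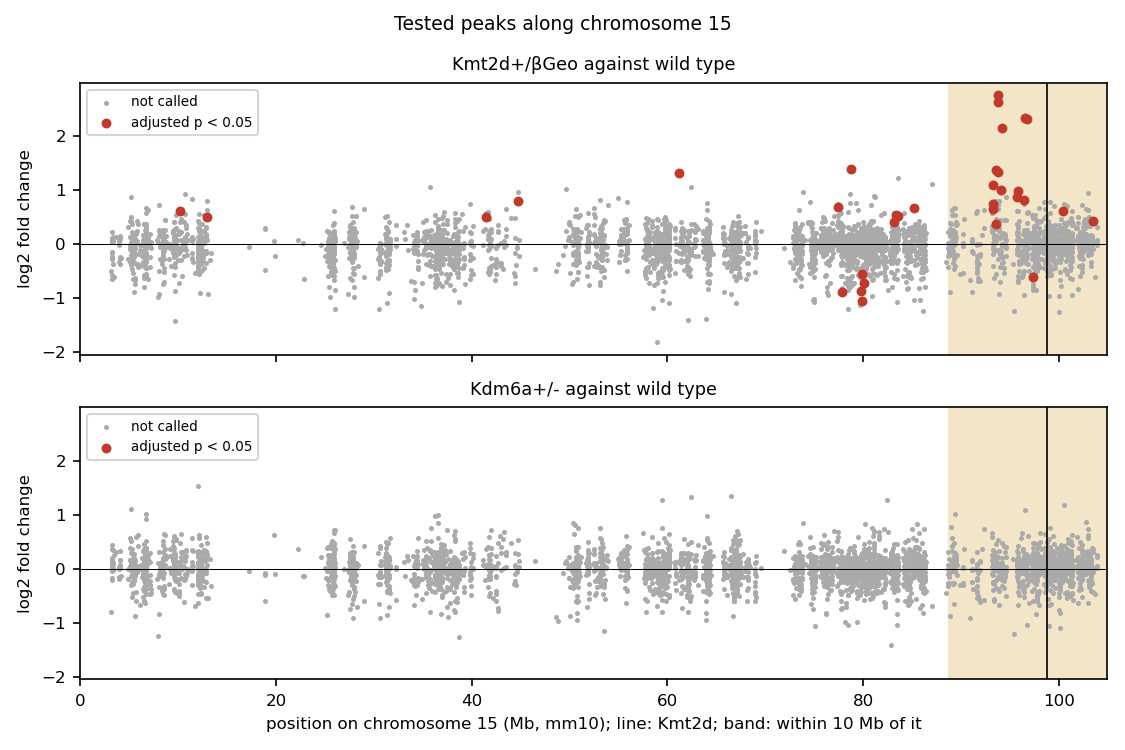
Log2 fold change of tested peaks (points) along chromosome 15 (position in Mb, mm10) for Kmt2d+/βGeo (top) and Kdm6a+/- (bottom) against wild type, with called peaks in red, the Kmt2d gene as a line and the 10 Mb on either side shaded. In the top panel 17 of the 18 called peaks in the shaded band are higher, and in the bottom comparison edgeR called no peak on any chromosome.

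Genes of T cell identity and function were tested at their gene ends. Among 12 naive and central memory genes, 1 rose: Foxp1, a transcription factor of T cell quiescence (6:99520229-99523774), at a log2 fold change of 0.35 ± 0.08 (adjusted p = 0.0335 over all peaks and 0.000951 adjusted over the list alone). Lef1 (0.32) and Satb1 (0.18) did not pass. Of 20 trafficking and integrin genes, 1 fell over all peaks, Itgae, which encodes the αE integrin (11:73090482-73091241, -0.75 ± 0.18, adjusted p = 0.0486). Adjusted over the list alone, 2 of the 20 fell, Itgae (0.00308) and the chemokine receptor gene Ccr6 (-1.0, 0.035), and 1 rose, Ccr5 (0.43, 0.0424). Of 20 effector and memory genes, 0 passed over all peaks and 1 rose adjusted over the list alone, the transcription factor gene Eomes (0.35, 0.012), while Cxcr3 (0.37) did not pass. Eomes passed over all peaks without wild-type replicate 6 (adjusted p = 0.0218) or 3 (0.0408), without the deep libraries (0.0144) and with a term for them (0.00542), in a range up to 0.653 over its alternatives. None of the 22 T cell receptor and lineage genes passed with edgeR, with Cd3e and Cd3g both at 0.34 and 3 genes at an unadjusted p under 0.05. Over all peaks Cd3g passed without the deep libraries (adjusted p = 0.036, up to 0.892 over its alternatives) and with a term for them (0.0421), and Cd3e without them (0.0267, up to 0.929). None of the 11 exhaustion and aging genes, 9 regulatory T cell genes, 17 immediate early genes, 24 cell cycle genes or 35 ribosomal protein genes passed in edgeR, over all peaks or adjusted over the list alone. At an unadjusted p under 0.05 these 5 lists held 0, 0, 0, 2 and 2 genes. The Foxp1 call ended in 11 of 17 runs that left out 1 library, Kmt2d+/βGeo replicate 2, 3, 4 or 7 or wild-type replicate 1, 2, 4, 7, 8, 10 or 11, with an adjusted p of up to 0.248 (without Kmt2d+/βGeo replicate 7). The Itgae call ended in 14 of 17, without Kmt2d+/βGeo replicate 3, 4, 5, 6 or 7 or wild-type replicate 1, 3, 4, 5, 6, 7, 10, 11 or 12, with an adjusted p of up to 0.145 (without Kmt2d+/βGeo replicate 6). With loess, with limma voom, with a replicate-number block and in either name format alone both calls ended as well, in a range up to 0.62 for Foxp1 and 0.54 for Itgae.

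Chromatin regulators and genes they act on were tested as lists of their own. Of 30 Polycomb complex genes, 1 fell adjusted over the list alone, Cbx7, a reader of H3K27 methylation (-0.67, adjusted p = 0.0242), and 0 over all peaks, although Cbx7 passed there with 2 surrogate variables (0.000502) and with the deep-library term (0.0176), in a range up to 0.937 over its alternatives. None of the 17 genes of H3K4 methyltransferase complexes and H3K27 demethylases passed with edgeR either way, and 0 had an unadjusted p under 0.05. None of the 24 acetylation and DNA methylation enzyme genes passed, with Tet2 at 0.20 and Tet1 at 0.30. The 26 Polycomb-target developmental transcription factor genes changed as a set in either direction (fry mixed test, adjusted p = 0.00395), but camera gave an adjusted p of 0.247. None of them passed alone, and the 6 with an unadjusted p under 0.05 were all higher, among them Hoxa1 (0.29), Hoxa9 (0.31) and Hoxa5 (0.69). In the directional fry test the smallest adjusted p over all 19 lists was 0.142, so this set did not pass it. Of 21 interferon genes, 1 rose adjusted over the list alone, Ifi44 (0.80, adjusted p = 0.0087), and 0 over all peaks, where Ifi44 passed in 4 of its 35 alternatives, DESeq2 (adjusted p = 0.0257), 2 surrogate variables (0.0358), loess (0.0422) and the deep-library term (0.0443), and in none of the others. None of the 10 X-escape genes passed with edgeR, and 1, Jpx (0.19), had an unadjusted p under 0.05.

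Marker genes of other blood cells were measured beside these. The 15 B cell genes were lower as a set in camera (median log2 fold change -0.22, adjusted p = 7.83e-05), but not with an estimated correlation (adjusted p = 0.811). None of them passed alone, with Ciita at -0.95, Cd79b at -0.36 and Cr2 at 0.33. Of 9 NK cell genes, 1 rose adjusted over the list alone, the kinase-like gene Styk1 (0.33, adjusted p = 0.00549), and 0 over all peaks, where it passed with DESeq2 (0.0405, up to 0.791 over its alternatives). None of the 18 myeloid and 8 erythroid genes passed with edgeR, and 0 of either list had an unadjusted p under 0.05. For 9 of the 19 lists, none of them called, the median or mean had another sign than the camera test, which compares a list with the gene-end peaks of all other genes.

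The number of calls depended on the libraries used. The unadjusted p was under 0.05 at 8649 peaks, where 5% of the tested peaks are 4653. Redrawn group labels also went past 4653. In 5 splits with all deep libraries in the group of 6 and 0 calls, this count was 5404 to 15678. The count of 8649 is therefore no sign of a group difference by itself. Leaving out Kmt2d+/βGeo replicate 7, 5 or 3 gave 150, 192 or 193 calls, leaving out the deep libraries gave 506, and the T and CD90-2 name formats alone gave 36 and 8 calls. Of the 302 calls 69.9% were higher, against 53.8% of 275 with total counts (148 higher, 127 lower) and 439 of 854 with surrogate variables. Without Kmt2d+/βGeo replicate 7, 58% of the 150 calls were higher (87 higher, 63 lower), and 124 of the 302 calls were kept.

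Kdm6a+/- was compared with wild type to ask the same of a copy of the demethylase gene. No peak passed in edgeR, at a smallest adjusted p of 0.0681, and the peaks named here did not pass in that fit. A peak in Slc47a1, an organic cation transporter gene (11:61355371-61356130), had 7.38 ± 1.48 CPM (SD, n = 5) against 3.65 ± 0.756 in wild type (n = 11), and a peak in Crbn, the gene of a ubiquitin ligase substrate receptor (6:106792814-106794915), had 27.8 ± 3.01 against 42 ± 5.98. Their log2 fold changes were 1.00 ± 0.18 (adjusted p = 0.0681) and -0.63 ± 0.12 (adjusted p = 0.0765).

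The other highest-ranked positive changes were in Atp6v1e1, a proton pump gene (6:120799466-120800444, 0.73 ± 0.13), at the ends of Susd4 (0.90 ± 0.16) and Gm21814 (0.75 ± 0.13), and in Lpp (16:24651686-24652698, 0.81 ± 0.16). The first 3 had an adjusted p of 0.0681 and Lpp one of 0.137. Negative changes ranked highest in Bbs9, a gene of primary cilia (9:22654937-22656330, -0.82 ± 0.17), and near Etv6 (6:134302038-134302289, -1.73 ± 0.37), Vmn1r15 (6:57271201-57272965, -0.95 ± 0.2) and Atp23 (10:126501833-126503188, -0.73 ± 0.16). Their adjusted p-values were 0.319, 0.342, 0.342 and 0.395. All of these but Etv6 passed in some of their 33 alternatives, among them DESeq2 and 2 surrogate variables: Atp6v1e1 in 10 (adjusted p of 0.000374 to 0.798 over its alternatives), Slc47a1 in 8 (0.000379 to 0.506), Crbn in 8 (0.000168 to 0.506), Vmn1r15 in 5, Susd4 and Gm21814 in 4 each, and Lpp, Bbs9 and Atp23 in 2 each. With no name-format term edgeR itself called Slc47a1, Atp6v1e1, Crbn, Susd4, Gm21814 and Vmn1r15. The count of 0 came with 4002 peaks at an unadjusted p under 0.05, where 5% of the tested peaks are 4653, while DESeq2 called 35 peaks and limma voom 8.

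None of the fixed-list genes passed over all peaks with edgeR. In camera, 20 effector and memory genes were lower (median -0.13, adjusted p = 1.73e-06), but not with an estimated correlation (adjusted p = 0.25). Ccl5, a chemokine of memory T cells, had -0.76, the only member with an unadjusted p under 0.05. The 15 B cell genes were lower too (median -0.22, adjusted p = 6.18e-07), which an estimated correlation ended (adjusted p = 0.239). Their members Pax5 and Cd19 had -0.55 and -0.68. The 9 NK cell genes were lower (median -0.13, adjusted p = 0.00503), with an adjusted p of 0.239 with an estimated correlation. Of these, 1 fell adjusted over the list alone, Ncr1, an activating receptor gene of NK cells (7:4337439-4338178, -1.04 ± 0.31, 0.018).

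Polycomb-target developmental transcription factor genes were higher (median 0.16, adjusted p = 0.00503), but not with an estimated correlation (adjusted p = 0.376). Hoxb2 had 0.62 and Six1 0.32, and neither passed. The 20 trafficking genes were lower in camera (median -0.05, adjusted p = 0.0251), again not with an estimated correlation (adjusted p = 0.836), with Ccr6 at -0.85. Of the 12 naive genes 0 passed, and Foxp1 and Tcf7 both had 0.22. The camera test called none of the other 13 lists, in which 0 genes passed adjusted over the list alone by edgeR and 2, Cd6 (0.30) and Ikzf4 (0.53), had an unadjusted p under 0.05. The share of counts at gene ends was 53.62 ± 0.9206% in Kdm6a+/- (n = 5) and 52.61 ± 0.6607% in wild type (n = 11; two-sided exact permutation p = 0.0128, adjusted p = 0.23 over 18 tests). Within the T format it was 53.62 against 52.82% (exact permutation p = 0.151).

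The models were compared directly to test where they differ. Mfng was 3.02-fold higher in Kmt2d+/βGeo than in Kdm6a+/-, at 13.3 ± 2.46 CPM (SD, n = 6) against 4.28 ± 0.886 (n = 5). A region 135975 bp from Lrfn5, a synaptic adhesion gene (12:61993903-61995232), was 2.85-fold higher, at 9.4 ± 2.31 against 3.57 ± 0.419 CPM. The peaks in Ntrk2 were lower, by 2.8-fold at 13:59025355-59026251 (1.24 against 3.54 CPM). Of 19 peaks called by edgeR, 13 were higher and 6 lower in Kmt2d+/βGeo.

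The log2 fold changes of Mfng and the Lrfn5 region were 1.60 ± 0.17 (adjusted p = 6.17e-06) and 1.51 ± 0.19 (adjusted p = 0.000106). A region 73564 bp from Slc38a2 (15:96773292-96773670) had the largest difference, 3.35 ± 0.4 (adjusted p = 2.81e-05), at 3.75 against 0.373 CPM. The gene end of Kitl had 1.43 ± 0.25 (adjusted p = 0.00942), a peak in Pald1 (10:61327138-61328718) 1.26 ± 0.17 (adjusted p = 0.000214), and Gxylt1 1.21 ± 0.16 (adjusted p = 0.000207). The gene ends of Samd3 (10:26229226-26230192) and Map2 had 1.12 ± 0.18 (adjusted p = 0.00364) and 1.04 ± 0.16 (adjusted p = 0.00225). Further gains were in Cblb, a ubiquitin ligase gene that restrains T cell activation (16:52083346-52084553, 1.19), in N4bp1 (8:86853566-86854301, 1.00) and in Thsd7a (6:12314986-12316034, 0.81).

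Besides Ntrk2, peaks were lower in Pax7, a muscle stem cell transcription factor gene (4:139828568-139829470, -1.28 ± 0.25, adjusted p = 0.0469), in Ndst1, a heparan sulfate enzyme gene (18:60727206-60727856, -1.21 ± 0.22, adjusted p = 0.0241), near Tbx3 (-1.0 ± 0.15, adjusted p = 0.0022) and near Pced1b (15:97424102-97425612, -0.71 ± 0.13, adjusted p = 0.0133). In all of these the 6 Kmt2d+/βGeo libraries lay beyond the Kdm6a+/- range, except in Cblb, where 5 did. With 1 library left out, the calls of N4bp1, Thsd7a, Cblb, Pax7, Ndst1 and Pced1b ended in 10, 9, 8, 8, 5 and 3 of 11 runs. The highest adjusted p-values came without Kdm6a+/- replicate 5 for N4bp1 (0.181), without Kmt2d+/βGeo replicate 3 for Thsd7a (0.247), without Kdm6a+/- replicate 1 for Cblb (0.239) and Ndst1 (0.0937), and without Kdm6a+/- replicate 2 for Pax7 (0.302) and Pced1b (0.0662). The Kitl call ended without Kdm6a+/- replicate 1 (adjusted p = 0.0891) or 2 (0.0523). With a replicate-number block the calls of Pald1, Samd3, Map2 and Tbx3 ended too (0.0545, 0.0958, 0.0958 and 0.0626), and that of 13:59011231-59011968 in Ntrk2, which also ended with the T format alone and with only the groups compared (up to 0.405). The unadjusted p was under 0.05 at 4465 peaks, where 5% of the tested peaks are 4653 and splits with redrawn labels gave 1302 to 7860.

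No fixed-list gene passed over all peaks in edgeR between the models. In camera the 20 effector and memory genes were higher in Kmt2d+/βGeo (median 0.23, adjusted p = 1.68e-07), but not with an estimated correlation (adjusted p = 0.277). Of these, Eomes rose adjusted over the list alone (0.38, 0.0343), while Klrg1 (0.76) and Ccl5 (0.60) did not pass. The 9 NK cell genes were higher too (median 0.12, adjusted p = 0.0461), which an estimated correlation ended (adjusted p = 0.277), with Ncr1 passing adjusted over the list alone (1.03, 0.0256). Of 30 Polycomb complex genes, 1 was lower adjusted over the list alone, Cbx7 (-0.96 ± 0.21, 0.00213). Over all peaks Cbx7 passed with 2 surrogate variables (adjusted p = 0.00103), DESeq2 (0.0241) and no name-format term (0.0478), in a range up to 1 over its alternatives. Of 20 trafficking genes, Ccr5 was higher (0.74, 0.00655) and Itgae lower (-0.68, 0.0159), both adjusted over the list alone. The other 15 lists had no gene that passed adjusted over the list alone and no camera call.

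Fold changes of both models against the same wild-type libraries went together. Across the 93053 peaks, which are not independent replicates, Pearson's r was 0.442 and Spearman's rho 0.433. Sharing the wild-type libraries alone gave a mean r of 0.405 (range 0.4 to 0.411) in 20 simulations of unchanged groups. The simulations drew each peak independently, without the structure of the real libraries, so this range understates the spread of r. With separate wild-type libraries for each model r was 0.051 (range -0.088 to 0.165 over 20 draws, SD 0.075). The observed r lay 0.0372 above the simulated mean, less than this SD, so it is no sign of agreement beyond the shared libraries. Of the 302 peaks called in Kmt2d+/βGeo, 270 (89.4%) had the same sign in Kdm6a+/-, with a median log2 fold change there of 0.28 for the 211 higher and -0.31 for the 91 lower peaks. With separate wild-type libraries 14 to 98 peaks were called and 62.2 to 78.9% of them had the same sign (6 draws).

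**Figure D3:**
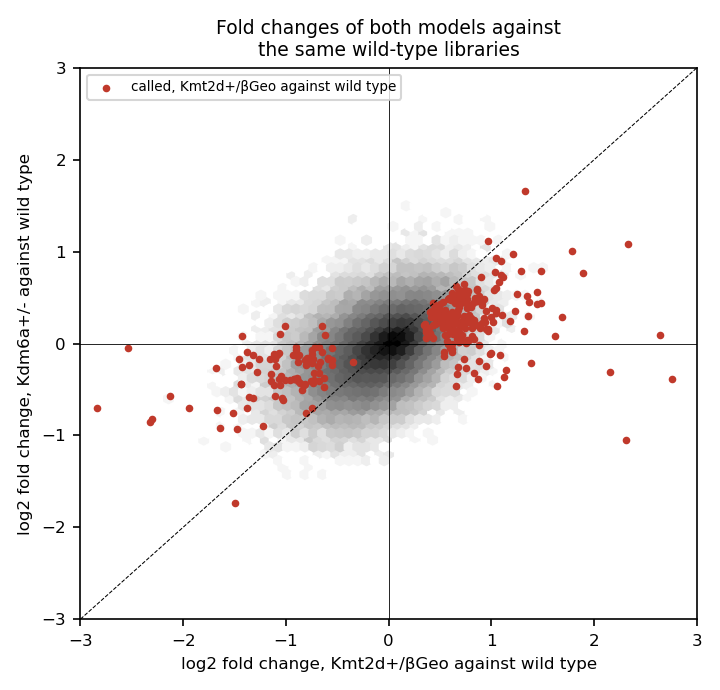
Log2 fold change against wild type in Kmt2d+/βGeo (x axis) and Kdm6a+/- (y axis) for 93053 tested peaks (grey density), with the 302 peaks called in Kmt2d+/βGeo as red points and equal changes as a dashed line. Of the red points, 270 have the same sign in both models, which share their wild-type libraries.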

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

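Chosen only after the results were seen were the tests of lost reads and of a segment passed on near Kmt2d, the test of a shift at all gene ends, the total-count share of gains, the odds ratios at gene ends with loess and without the deep libraries, and the fits without these libraries.

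Called peaks of Kmt2d+/βGeo against wild type lay close together within 10 Mb of Kmt2d, where 17 of the 18 called were higher. Reads of another strain lost in mapping would have lowered counts, so these 17 gains argue against that loss as the cause of the pattern. A copy number change of the whole segment is argued against by the median log2 fold change of 0.028 over all 907 tested peaks there. Its 95% bootstrap interval (0.009 to 0.042) was over resampled peaks, so it does not measure the spread between libraries. A copy number change of a shorter stretch, such as that of the called peaks 4.63 to 5.58 Mb from Kmt2d, could leave this median as it is. The median cannot decide on such a change. A chromosome segment of another strain passed on with the targeted allele cannot be told apart from an effect of Kmt2d on its own surroundings: the odds ratio of 6.55 is the pattern itself, and among the 889 peaks there that were not called, 8.44% had an unadjusted p under 0.05 against 9% elsewhere (odds ratio 0.931, 95% interval 0.724 to 1.18). No sequence was examined, the labels give C57BL/6J for every library, and both explanations stay open, as does a copy number change of a shorter stretch.

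Gains outnumbered losses in Kmt2d+/βGeo and were enriched at gene ends. The excess of gains was smaller without Kmt2d+/βGeo replicate 7, where 58% of 150 calls were higher (87 higher, 63 lower). Without replicate 7 and the deep libraries, 67.9% of 168 calls were higher. The excess also depended on scaling, since with total counts 53.8% of 275 calls were higher. With total counts the median log2 fold change over all tested peaks was -0.051, against -0.000157 with TMM factors. Such a shift lowers the share of gains by itself, so this test cannot decide whether scaling made the excess. A trend with abundance alone is argued against by the 67.5% of 345 calls that were higher after loess normalisation. At gene ends that trend cannot be told apart from a change at these regions, because loess lowered the odds ratio from 2.55 to 1.41 (95% interval 1.01 to 1.93), an interval that leaves room for either. The deep libraries and Kmt2d+/βGeo replicate 7 together are argued against as the whole cause by an odds ratio of 3.09 (2.07 to 4.57) without them, but a part of the deep libraries in the size of the enrichment cannot be told apart from a change at gene ends, since without them alone it was 1.64 (1.29 to 2.07). A general rise at gene ends is argued against as the whole cause by their median log2 fold change of 0.047, against -0.000157 over all tested peaks. The 95% bootstrap interval of 0.047 (0.045 to 0.049) was over resampled peaks, so it does not measure the spread between libraries. However, in the T format the share of counts at gene ends was 53.98 against 52.82%, a difference that did not pass (unadjusted exact p = 0.0159, adjusted 0.285). A response to the loss of a Kmt2d copy stays open as a hypothesis.

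Neighbouring peaks in and past Ntrk2 were lower in Kmt2d+/βGeo, with 5 of 6 tested peaks between 59011231 and 59243276 on chromosome 13 called. Besides those named above, these were 13:59028265-59028990 (-2.32 ± 0.27, adjusted p = 5.65e-06) and 13:59242740-59243276 (-1.36 ± 0.27, adjusted p = 0.013). A single library is argued against as the cause, since the peak at 13:59025355-59026251 kept an adjusted p of at most 2.29e-07 in the 17 runs that left out 1 library. A copy number change of the segment cannot be told apart from a change in accessibility, because the single uncalled peak (-1.65 ± 0.41, adjusted p = 0.0659) is too few to decide, although -2.3 ± 0.21 lies below the -1 that loss of 1 of 2 copies gives. An effect of Kmt2d on the region stays open as untested.

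Among 94 groups of values, 6 held a single library that stood apart from the others, where chance gives about 4.7. Kmt2d+/βGeo replicate 4 had 6.45 CPM at Samd3 (others 8.95 to 10.4), replicate 7 had 21.4 at Adgrl2 (8.04 to 12.4) and replicate 3 had 3.31 at Dysf (0.919 to 1.81). Kdm6a+/- replicate 4 had 3.58 CPM at Sufu (others 2.35 to 2.65) and replicate 5 had 1.96 at N4bp1 (3.35 to 3.56). Replicate 5 also had 55.2% of its counts at gene ends (others 52.9 to 53.5%).

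The models differed by edgeR's test of the difference at 17 named peaks. The log2 fold change of Kmt2d+/βGeo against Kdm6a+/- was 3.35 near Slc38a2, 1.6 at Mfng, 1.51 near Lrfn5, 1.43 at Kitl, 1.26 in Pald1, 1.21 in Gxylt1, 1.19 in Cblb, 1.12 at Samd3, 1.04 at Map2, 1.00 in N4bp1 and 0.81 in Thsd7a. It was -1.55 and -1.49 in Ntrk2, -1.28 in Pax7, -1.21 in Ndst1, -1.0 near Tbx3 and -0.71 near Pced1b.

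The 2 samples whose title and genotype label contradict each other, and whose column names side with the titles, also held signal above the wild-type range. The sample titled Kabuki syndrome type 1 replicate 1 and labelled wild type (27.8 M counts) had 13.1 CPM at Map2 (wild type 5.32 to 10.4), 14 at Mfng (3.71 to 6.23), 4.28 near Prickle1 (1.53 to 3.21), 9.94 in Adgrl2 (3.94 to 6.99), 4.02 at Kitl (1.11 to 3.43), 15 at Gm21814 (6.05 to 10.7) and 12.1 in Gxylt1 (3.64 to 6.29). The sample titled wild type replicate 9 and labelled Kmt2d+/βGeo (16 M counts) had 8.53 CPM at Mfng, 9.58 near Prickle1, 4.66 near Plk2 (wild type 1.51 to 4.01), 12.7 at both Gm21814 and Gxylt1, and 7.48 in Ntrk2 at 13:59011231-59011968 (3.55 to 5.34). Of the 10 named higher peaks, 7 lay above the wild-type range in the former and 5 in the latter, and of the 10 named lower peaks, 9 and 1 lay below it.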

How the results depend on the processing

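The fits with a term for deep libraries, without them, without them and Kmt2d+/βGeo replicate 7, and without peaks within 10 Mb of Kmt2d were chosen after seeing the data. For Kmt2d+/βGeo against wild type (302 calls), 8 alternatives stayed within 1.5 times: RLE 305, total counts 275, loess 345, no count filter 291, a mean of at least 20 counts 295, no name-format term 332, autosomes 282, and no peaks within 10 Mb of Kmt2d 281. Counts moved with DESeq2 (777), limma voom (191), 2 surrogate variables (854), the T format alone (36), the CD90-2 format alone (8), only the groups compared (175), the deep-library term (667), no deep libraries (506), neither these nor replicate 7 (168) and a threshold of 0.1 (600). Fewer libraries entered the fits by name format, by groups compared and without deep libraries, but whether that caused their moves was not tested. Without deep libraries the calls rose rather than fell. For the other moves the cause was not tested either. Leaving out 1 library gave 150 (Kmt2d+/βGeo replicate 7) to 440 (wild-type replicate 3) calls, with 192 and 193 without Kmt2d+/βGeo replicates 5 and 3.

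For Kdm6a+/- against wild type, edgeR gave 0 calls (4002 at an unadjusted p under 0.05) and 0 without any single library. Total counts gave 2, loess 3, DESeq2 35, limma voom 8, a mean of at least 20 counts 3, no name-format term 13, 2 surrogate variables 18, the deep-library term 1, no deep libraries 2, neither these nor Kmt2d+/βGeo replicate 7 5, and a threshold of 0.1 5. Between the models (19 calls) DESeq2 gave 67, 2 surrogate variables 88, the deep-library term 38, no peaks within 10 Mb of Kmt2d 10 and a threshold of 0.1 34, while leaving out 1 library gave 13 to 21. The cause was not tested, except that fewer peaks were tested in the fit without the 10 Mb. DESeq2 gave no adjusted p to 9022 peaks for Kmt2d+/βGeo and 46907 for Kdm6a+/- against wild type.

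With replicate number as a block (replicate block) the calls were 68 for Kmt2d+/βGeo and 7 between the models. The counts gave no sign that the numbers pair the samples, which the labels do not state. A mean correlation of -0.081 (-0.393 to 0.159) was found in 15 pairs with the same number. In 62 pairs with other numbers it was -0.016 (-0.457 to 0.59).

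Region classes called by camera were 1, 0 and 0 for Kmt2d+/βGeo, Kdm6a+/- and between the models. They became 0 for Kmt2d+/βGeo with loess and with an estimated correlation, and 2, 1 and 2 in the T format alone. Gene lists called were 1, 5 and 2. With an estimated correlation they were 0 in each comparison. With loess they were 3 for Kmt2d+/βGeo and 4 between the models, where the T format, the replicate block and a gene-end distance of 2 kb gave 1 each. Measures per library with an unadjusted exact p under 0.05 were 1, and 2 in the T format alone. For all of these the cause was not tested. The correlation between models was 0.051 with separate wild-type libraries, against 0.442. Simulated unchanged groups that shared the wild-type libraries gave 0.405 (0.4 to 0.411), with each peak drawn independently. Sharing these libraries can thus account for most of the move.

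Named peaks kept their direction and their side of the threshold in 1735 of 1846 tests for Kmt2d+/βGeo, 767 of 820 for Kdm6a+/- and 894 of 1001 between the models. A call was lost in 82, 0 and 93 tests and gained in 14, 45 and 3, and no called peak changed sign. The gained calls for Kmt2d+/βGeo were Eomes, Cd3g and Cd3e without the deep libraries, the former pair also with the deep-library term, Eomes without wild-type replicate 6 or 3 (adjusted p 0.0218 to 0.382 over the 17 runs that left out 1 library), Cbx7, Ifi44 and Styk1, and between the models Cbx7 in 3 alternatives. A correction for GC content and CpG-island classes were not run, since no genome sequence was used here. At this spread 27% of simulated 1.5-fold changes were recovered for Kdm6a+/-, all simulated at peaks above the median mean count. Changes of that size were thus mostly not detectable at such peaks, and peaks of lower count were not tried.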

Other observations

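The view by 20 Mb bins of the genome, the overlap of the models and the last 16 of the 64 splits below were chosen after the results were seen.

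The gene ends of Susd4 and Gm21814 ranked high in both models. Susd4 had 5.47 CPM in wild type, 11.6 in Kmt2d+/βGeo and 10.1 in Kdm6a+/-, and Gm21814 had 7.97, 17.7 and 14.8. Both were called by edgeR in Kmt2d+/βGeo. In Kdm6a+/- both had an adjusted p of 0.0681, and passed with DESeq2, limma voom, no name-format term and 2 surrogate variables (0.000551 to 0.628 over the alternatives of Susd4 and 0.000379 to 0.506 over those of Gm21814). At an adjusted p under 0.1 the models shared 3 higher peaks and 1 lower peak. At an unadjusted p under 0.05 they shared 652 higher and 623 lower peaks. These came from 4349 higher and 4300 lower peaks in Kmt2d+/βGeo and 1687 and 2315 in Kdm6a+/-. Simulated unchanged groups with the same wild-type libraries shared 347 and 268.5 on average, but the lengths of their lists were not kept. The real Kmt2d+/βGeo lists held 8649 peaks, where 5% of the tested peaks are 4653, and longer lists share more peaks. The excess therefore cannot tell shared changes from longer lists. Crbn had 42 CPM in wild type, 31.7 in Kmt2d+/βGeo and 27.8 in Kdm6a+/-.

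Of 139 bins of the genome, the first 20 Mb of chromosome 14 had the highest share of called peaks in Kmt2d+/βGeo, 8 of 359 (2.23%). The bin from 80 Mb on chromosome 15, which holds Kmt2d, came next with 21 of 1142 (1.84%). Chromosome 15 as a whole held 4072 of the 93053 tested peaks and 35 of the 302 calls, 28 of them higher. Of these 35, 18 lay within 10 Mb of Kmt2d, and the others, Mfng among them, lay outside. The test of a segment passed on with the targeted allele covered only the peaks within these 10 Mb.

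Group labels redrawn within name format gave 64 splits for each comparison, the real one included. That number was chosen after a first 48 of them, and then a longer trial that took too long to keep, had been seen. In the part of the trial that was not kept, no further split gave as many as the real calls for Kmt2d+/βGeo or between the models, but a split for Kdm6a+/- called more than the highest other of 0 given here. For Kmt2d+/βGeo against wild type, 3 of the 64 gave as many as the real 302 calls (4.69%) and the highest other gave 2721. Chance was excluded only by the limit of 5%, and the exact (Clopper-Pearson) 95% interval of that share, 0.977 to 13.1%, leaves room for more. The other splits with as many, at 771 and 2721 calls, point to a structure of the samples that gave more calls than the real grouping did. Both put the deep libraries (wild-type replicates 3 and 6 and Kmt2d+/βGeo replicate 2) together in the group of 6, but so did 5 others in which edgeR called 0 peaks (5404 to 15678 at an unadjusted p under 0.05), so their place alone does not account for these calls. Without these libraries the real comparison gave 506 calls. Between the models 1 of 64, the real split itself, gave as many as the real 19, with a highest other of 1. Its share of 1.56% was under the limit of 5%, but the interval reached 8.4%, so chance was not firmly excluded. Of 126 possible splits 64 were drawn, and the Kmt2d+/βGeo libraries of the CD90-2 format kept their group in all of them. For Kdm6a+/- against wild type, 64 of 64 splits gave at least the real 0 calls by edgeR, with a highest other of 0 (35 calls by DESeq2 and 8 by limma voom in the real comparison), as any split must, so they say nothing of chance. Of these 64, 10 gave at least the real 4002 peaks with an unadjusted p under 0.05, with a highest other of 6173, so chance could not be excluded for that count.

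For gene lists called by camera in each comparison, and for the region class called in Kmt2d+/βGeo, chance could not be excluded. As many lists as the real 1, 5 and 2 were called in 58, 17 and 49 of the 64 splits for Kmt2d+/βGeo, Kdm6a+/- and between the models, with 9, 8 and 9 as the highest others. As many classes as the real 1 were called in 49 splits for Kmt2d+/βGeo, with a highest other of 4. For the real 0 of the other comparisons, 64 and 64 splits gave as many, as any split must, with 3 and 3 as the highest others, so these splits say nothing of chance.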
